A study of Drosophila melanogaster with 46 samples.

How the data were processed

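Small RNA libraries of Drosophila melanogaster ovarian somatic cells were analysed from 2 deposited tables. Of the 46 samples of the series, 11 have values in them; the 17 mRNA-seq and 18 ChIP-seq samples were not used here. The groups, the comparisons, the tests, the TE lists and the rule for named TEs were fixed before the data were examined, except where stated.

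The first table holds 124 TEs with sense and antisense values for 2 libraries each of input, Piwi-IP and CG9754-IP. Its header gives no unit: the deposited values were read as RPM, reads scaled to a library total of 1000000, since in each library every value was a whole multiple of 1 step (within 0.02 reads), and 1000000 divided by the step gave a total of 12493500 to 26138400 reads. The second table holds a deposited signal for 40 windows of 1 kb in each of flamenco and 20A, for 1 library each of GFP-KD, Armi-KD, Piwi-KD, SetDB1-KD and HP1-KD; per the file headers these are normalized piRNA counts. They were whole multiples of 1 step per library as well, which gives reference totals of 565429 to 1146906 reads, but the columns sum to more than 1000000 in 3 of the libraries, so the reference is another set of reads than all mapped reads, and the table does not name it. The submitters' notes name cutadapt 1.0, Bowtie 0.12.7, SAMtools 0.1.16, bedtools 2.16.1 and the genome build dm3, without their roles or order. How reads that match several TEs or loci were treated, the size range and the mismatches allowed are not stated in the sources used here, so related elements such as Stalker and Stalker4 may share reads.

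From the totals, a value of 0 with a floor of 3 reads allows up to 0.115 to 0.240 RPM in the TE table and a signal of up to 2.62 to 5.31 in the cluster table. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The spread between replicates was larger than counting error, with a chi-square per degree of freedom of 7.34 in input, 10.1 in Piwi-IP and 265 in CG9754-IP.

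TE values were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(RPM + 1), with the 6 libraries in 1 fit by group and 3 contrasts. TEs with a mean of at least 10 RPM over the 6 libraries were tested, 75 on the antisense strand, the main one, and 53 on the sense strand. The ratio of the strands, log2((sense + 1)/(antisense + 1)), was tested in the 89 TEs with a sum of both strands past the same filter. A Benjamini-Hochberg adjusted p under 0.05 in a contrast was the threshold, and the tests are two-sided. The 8 TE lists were tested with camera (preset correlation 0.01, lists with at least 3 tested members, adjusted over lists and contrasts of a strand). Their members in the table numbered 14 of 15 for gypsy-group, 8 of 10 for other gypsy-superfamily, 7 of 10 for BEL/Pao, 4 of 5 for copia, 5 of 6 for telomeric, 27 of 29 for non-telomeric LINE, 22 of 23 for DNA transposons and foldback and 17 of 18 for germline-dominant TEs. The last shares members with the other lists. Named TEs are, in each contrast, the 10 largest rises and 10 largest falls past the threshold whose replicates do not overlap, the 10 TEs with the highest Piwi-IP mean, and gypsy, ZAM, mdg1, gtwin, 297, Idefix, HeT-A, roo and the I-element whether or not they pass; elements named by a number (297, 412, 1731, 17.6 and 1360) are given in the text without their names: the most abundant TE is 412, the number-named gypsy-group element fixed in advance is 297, the other abundant number-named element is 17.6, the DNA transposon that rose against input is 1360, and the copia-type element that moved with copia on the antisense strand is 1731; the plot of sense levels names those it shows. No mock precipitate was among the libraries used here.

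For each knockdown, cluster sums and windows were compared with GFP-KD as ratios with an exact conditional binomial 95% interval from the implied reads (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). A window was called at a 2-fold limit if the larger of both libraries had at least 100 reads. The clusters 42AB, 38C and 80F, planned as a check for germline RNA, were not used here. The 3 windows with the largest rises and falls past the limit are named per knockdown. Plots were drawn with matplotlib 3.10.9.

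The tests were checked on simulated data. With a noise SD of 0.1 (log2) and 20 runs, limma recovered 92.5% of antisense TEs changed 1.5-fold and 98.8% of those changed 2-fold, with 0.45 false calls per run. Camera found a list raised 2-fold in 100% of 80 runs, and the window intervals covered the true ratio in 93.6% to 97.2% of runs in 8 settings. The simulated noise was equal in all groups and independent between TEs. In the data CG9754-IP varied most between replicates and TEs may vary together, so the limma and camera rates need not hold there.

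Alternatives were no filter and a filter of 100 RPM, pseudocounts of 0.1 and 10, rescaling of each library to the same total or by its median ratio over TEs (median-of-ratios factors from 128 values of both strands past the filter), a fit of only the 2 groups compared, a replicate block, each library left out in turn, the other strand and the sum of strands, camera with an estimated correlation, and for the clusters both rescalings, minima of 10 and 1000 reads and a 1.5-fold limit. The sense strand as a result of its own, the strand ratio, the rescaled fit of only the 2 groups compared, the rescaling by the median ratio, the rescaled lists, the lists with no filter and the separate cluster and window results were added after seeing the data. The planned edgeR and DESeq2 tests and TMM factors were not run. All values came out as whole reads, but a column of the TE table held at most 18 to 30 values of 1 to 20 reads per library, under the minimum of 100 that was required before a count model was used on reads derived from RPM; the implied reads served for intervals and floors.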

Results

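Small RNAs of Drosophila ovarian somatic cells (OSC, a cultured line of follicle cell origin with an active Piwi pathway) were measured in 11 libraries. Of these, 6 give the small RNAs of transposable elements (TEs) on each strand: 2 libraries from a Piwi immunoprecipitate (Piwi-IP), 2 from a CG9754 immunoprecipitate (CG9754-IP) and 2 of input RNA. The other 5 libraries give the small RNA signal along the piRNA clusters flamenco and 20A, with 1 library each of cells depleted of Armi, Piwi, SetDB1 or HP1 and of the control knockdown against GFP, taken 4 days after transfection. A further 17 mRNA-seq and 18 ChIP-seq samples of the series were not analysed here. The totals to which the TE values were scaled were 18861900 and 15327200 reads for input, 15064800 and 12493500 reads for Piwi-IP, and 26138400 and 19874200 reads for CG9754-IP. Nothing in the labels says whether the paired libraries of a group came from separate cultures. Every p-value therefore rests only on the spread between these libraries. Limma pools that spread over the groups and draws it towards a trend across TEs. A small p-value can thus rest on the spread of other TEs and groups, not on that of the TE in the groups compared.

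Antisense small RNAs, the strand that can pair with TE transcripts, made up most of the TE signal in all 3 kinds of library. Their sum over all TEs of the table was 211500 ± 231 RPM in input (reads scaled to a library total of 1000000; mean ± SD, n = 2, as for all TE values that follow), 237427 ± 1576 in Piwi-IP and 178217 ± 4295 in CG9754-IP. The sense sum was 12286 ± 121 RPM in input, 13143 ± 129 in Piwi-IP and 18587 ± 535 in CG9754-IP. Accordingly, the antisense percentage of the TE signal was 94.5 ± 0.057 in input, 94.8 ± 0.016 in Piwi-IP and 90.6 ± 0.040 in CG9754-IP. With 2 libraries against 2, an exact permutation test of any 1 of these values cannot give a p below 0.333. The gypsy-group LTR elements, retroviral-like elements that include gypsy, ZAM, gtwin and Idefix, held 46.6% ± 0.35 of the antisense signal in input, 47.5% ± 0.030 in Piwi-IP and 48.8% ± 2.29 in CG9754-IP. The list of TEs commonly described as germline-dominant piRNA targets, fixed as a check for germline RNA in this somatic line, held 3.34% ± 0.010, 3.34% ± 0.040 and 4.30% ± 0.15.

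The first comparison asks how closely the small RNAs bound by Piwi, the nuclear Argonaute protein of the pathway, follow those of the input RNA. The antisense profile of Piwi-IP was close to that of input: gtwin had 35163 ± 928 RPM in Piwi-IP and 30040 ± 447 in input, mdg1 had 21416 ± 733 and 20307 ± 67, and gypsy had 15421 ± 244 and 13062 ± 99. The most abundant TE, 1 of the elements named by a number, had 37378 ± 53 and 34299 ± 528. The gypsy-group element fixed in advance that is named by a number had 2461 ± 5.04 and 2210 ± 31 RPM (log2 change 0.16, adjusted p = 0.264). The foldback element FB4 (Repbase_FB4 in the table) was the 1 TE of 75 tested that passed the limma threshold, lower in Piwi-IP at 13.99 ± 0.31 RPM against 29.7 ± 0.62 in input (log2 change −1.04, adjusted p = 0.0143). Its adjusted p was above 0.05 when any 1 of the 4 input and Piwi-IP libraries was left out (0.126 to 0.207). An unadjusted p under 0.05 was reached by 19 TEs as deposited, by 2 with either rescaling of the libraries (to the same TE total, or by the median ratio of each library over the TEs), and by 3 to 9 without 1 of the input or Piwi-IP libraries. The median log2 change over the tested TEs was 0.16, and 0.00 once each library was rescaled to the same TE total. The count rested on the CG9754-IP libraries, which share the estimate of the spread: without CG9754-IP replicate 1 the test called 47 TEs (46 higher in Piwi-IP), without replicate 2 it called 45 (44 higher), and a fit of the 4 input and Piwi-IP libraries alone called 46 (45 higher), or 9 (3 higher, 6 lower) after rescaling. It called 0 TEs without either input library or without Piwi-IP replicate 2.

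Among the 8 fixed TE lists, that of DNA transposons and foldback elements was lower in Piwi-IP than the other TEs by limma's camera test (adjusted p = 0.00984 with the preset correlation, adjusted p = 0.645 with an estimated correlation, and 0.118 with no filter on low values). Its 6 tested members had a median log2 change of 0.05, above 0 but below the median of 0.16 over all tested TEs. The list median was −0.11 after rescaling to the same TE total. FB4 was its 1 member past the threshold, also when adjusted over the list alone. Of the gypsy-group list, 0 of 14 members passed by limma. The copia list, at a median of −0.11, had an adjusted p of 0.0586, and passed without Piwi-IP replicate 2 (0.0128) or without CG9754-IP replicate 1 (0.00308) or replicate 2 (0.00412). The 3 telomeric TART elements, which maintain chromosome ends, had a median of 0.25, and of 0.08 after rescaling to the same TE total. As deposited all 3 passed when adjusted over the list alone and 0 when adjusted over all TEs, and after rescaling 0 passed with either adjustment. Without either input library 0 passed over the list alone, and without either Piwi-IP library 1 did.

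On the sense strand, 2 of 53 TEs tested were lower in Piwi-IP than in input. R1A1-element, a retrotransposon that inserts into ribosomal RNA genes, fell from 12.4 ± 0.039 to 2.80 ± 1.02 RPM (log2 change −1.85, adjusted p = 3.3e-06). FB4 fell from 34.6 ± 2.27 to 17.9 ± 1.33 RPM (log2 change −0.91, adjusted p = 1.3e-04). The number-named gypsy-group element fixed in advance had −0.47 (adjusted p = 0.0686), and passed as lower when rescaled to the same TE total (−0.62, adjusted p = 0.00167). Leaving out CG9754-IP replicate 1 or replicate 2 raised the count to 5 TEs (1 higher, 4 lower). Among the fixed lists, 0 passed camera on this strand (1 at an unadjusted p under 0.05, the gypsy-group list, with a median of −0.02).

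The second comparison asks whether the small RNAs that precipitated with CG9754, the Silencio protein that the series places between Piwi and heterochromatin, have the TE composition of those that precipitated with Piwi. On the antisense strand the profiles were similar in rank but not in level. Copia rose from 97.0 ± 4.43 RPM in Piwi-IP to 521 ± 97 in CG9754-IP (log2 change 2.40, adjusted p = 2.0e-04) and springer from 553 ± 25 to 2269 ± 516 (2.02, adjusted p = 4.6e-04). Several abundant LTR elements fell: mdg3 from 423 ± 29 to 147 ± 0.81 RPM (−1.52, adjusted p = 2.0e-04), rover from 15671 ± 450 to 7520 ± 552 (−1.06, adjusted p = 2.6e-04), Idefix from 10321 ± 25 to 5566 ± 764 (−0.90, adjusted p = 0.00124) and mdg1 from 21416 ± 733 to 13354 ± 1525 (−0.69, adjusted p = 0.00170). The most abundant TE fell from 37378 ± 53 to 25330 ± 2592 RPM (−0.57, adjusted p = 0.00207; −0.22 rescaled to the same TE total, adjusted p = 0.0395), and another abundant number-named element from 7462 ± 67 to 4240 ± 313 (−0.82, adjusted p = 4.6e-04). The number-named element fixed in advance fell from 2461 ± 5.04 to 1744 ± 185 RPM (−0.50, adjusted p = 0.00446), and lost the call when rescaled to the same TE total (−0.15, adjusted p = 0.149). Gypsy had 17159 ± 2640 RPM in CG9754-IP against 15421 ± 244 in Piwi-IP (0.15, adjusted p = 0.267).

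In all, 47 of 75 TEs passed the limma threshold on the antisense strand, 7 higher and 40 lower in CG9754-IP. Without CG9754-IP replicate 1 these were 14 and 52, and without either Piwi-IP library 6 or 7 higher and 26 or 27 lower. The median log2 change over the tested TEs was −0.38, and between −0.47 and −0.28 with each library left out. When each library was rescaled to the same TE total, the median was −0.03 and 32 TEs passed, 16 higher and 16 lower, 23 of them among the 47. Rescaled by the median ratio of each library over the TEs instead, the median was −0.16 and 36 TEs passed, 10 higher and 26 lower, so the excess of falls depended on the scaling. Where the median ratio is not named, rescaled values were scaled to the same TE total. On these, copia (2.75), springer (2.37), DNAREP1 (1.80), FB4 (1.71) and G2 (1.12) remained higher, and mdg3 (−1.17), rover (−0.71), Dm88 (−0.71), Juan (−0.55), Idefix (−0.55), Quasimodo (−0.45), mdg1 (−0.34) and ZAM (−0.33) remained lower, all with an adjusted p under 0.05. The sign of gtwin depended on the scaling, with a log2 change of −0.20 (adjusted p = 0.0300) as deposited and 0.15 (adjusted p = 0.0944) when rescaled, or 0.02 by the median ratio, and the call was also lost without any 1 of the 4 input and Piwi-IP libraries. Gypsy passed as higher only when rescaled (0.49, adjusted p = 0.0251) or without CG9754-IP replicate 1 (0.30). Tirant (−1.34), transib4 (−0.93), the I-element (−0.77), Stalker4 (−0.61) and Stalker (−0.50) were lower as deposited but lost the call when rescaled or without either Piwi-IP library.

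The fixed lists describe where the antisense changes lay. Of 14 gypsy-group elements, 1 rose (springer) and 10 fell, with a median log2 change of −0.69, and −0.34 after rescaling (2 rose, 7 fell). Of the 8 other gypsy-superfamily elements, 7 fell, with a median of −0.59; rescaled, 1 rose and 4 fell, at −0.24. Of the 16 non-telomeric LINE elements, 1 rose (G2) and 9 fell, Juan among them, and after rescaling 4 rose and 4 fell. All 3 telomeric elements fell, with a median of −0.38, and after rescaling 0 of them passed, with a median of −0.03. In the copia list copia and 1 other element (0.88) rose and Dm88 fell, with either scaling. The BEL/Pao list (5 tested) and the DNA transposon list (6 tested, FB4 the riser) each had 1 member that rose and 1 that fell; after rescaling these lists had 1 and 2 rises and 0 falls. Of the 11 germline-dominant TEs tested, 2 rose (copia and the same copia-type element) and 5 fell, and after rescaling 3 rose and 0 fell. Adjusted over the list alone, the counts as deposited were the same except for 8 falls among the other gypsy-superfamily elements, 2 rises among the LINE elements and 0 rises in the BEL/Pao list. Camera called 0 of the 8 lists (1 at an unadjusted p under 0.05, the copia list, adjusted p = 0.208).

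Small RNAs antisense to roo, the most abundant BEL/Pao element, differed between the CG9754-IP libraries, with 2523 and 1260 RPM against 1662 ± 18 in Piwi-IP, and did not pass (log2 change 0.10, adjusted p = 0.796). Without CG9754-IP replicate 1 the log2 change was −0.40 (adjusted p = 9.7e-06), and without replicate 2 it was 0.60 (adjusted p = 1.2e-05), so the direction rested on 1 library. HeT-A, a telomeric element active in the germline, was below the filter at 2.18 ± 0.021 RPM in Piwi-IP and 5.06 ± 0.69 in CG9754-IP.

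**Figure D1:**
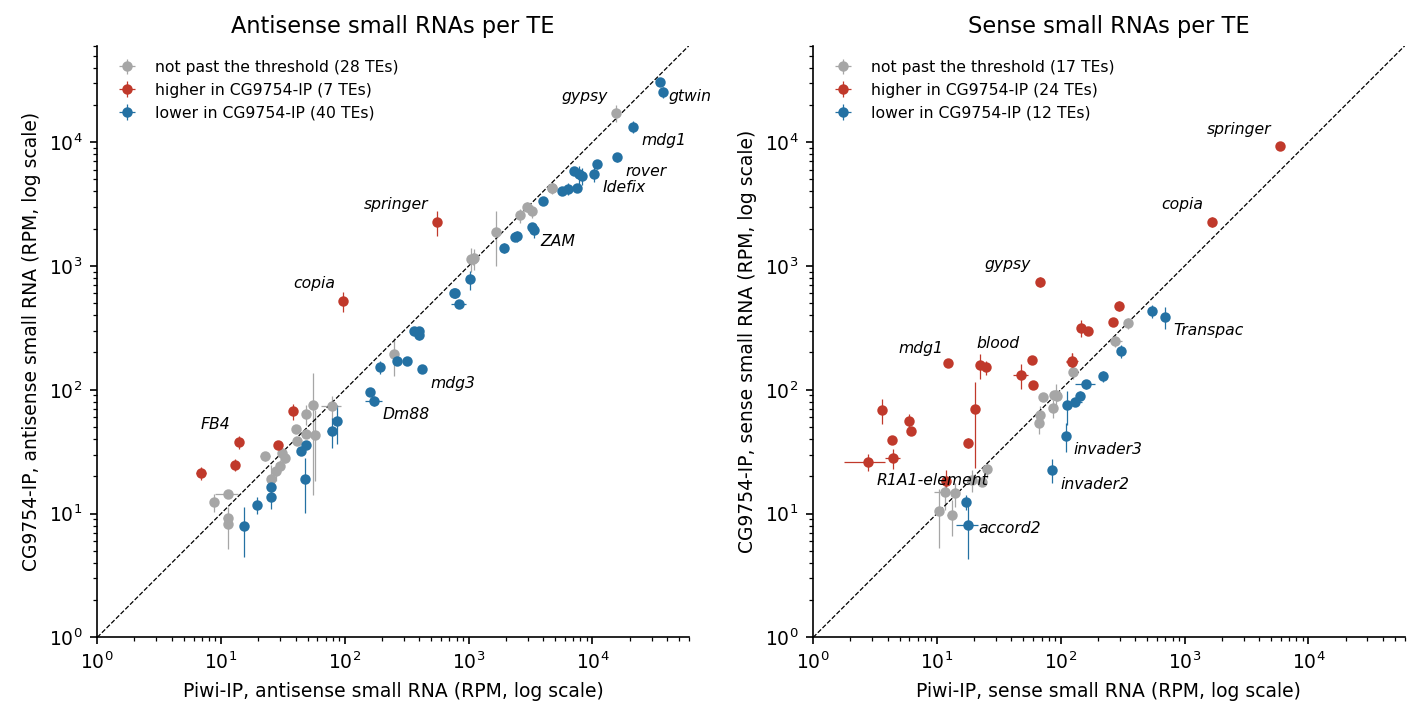
Mean small RNA level per TE in CG9754-IP (y axis, RPM, log scale) against Piwi-IP (x axis, RPM, log scale) for the 75 TEs tested on the antisense strand (left) and the 53 on the sense strand (right). Points are means of 2 libraries, bars are SD and the dashed line marks equal levels; on the values as deposited, most antisense points lie slightly under the line (40 lower, 7 higher), with copia and springer far above it, while on the sense strand 24 TEs lie above it past the threshold and 12 below.

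The sense strand showed larger changes. Gypsy sense small RNAs rose from 67.6 ± 3.17 RPM in Piwi-IP to 743 ± 67 in CG9754-IP (log2 change 3.44, adjusted p = 2.5e-18), mdg1 from 12.4 ± 0.42 to 165 ± 12 (3.63, adjusted p = 1.1e-17) and blood from 22.4 ± 0.43 to 158 ± 36 (2.75, adjusted p = 1.0e-14). HMS-Beagle (3.03), gypsy4 (2.91), R1A1-element (2.85), rover (2.74), the number-named element fixed in advance (2.55, from 25.0 ± 1.73 to 151 ± 19 RPM) and HMS-Beagle2 (2.42) rose as well, and the largest rise (3.90) was that of the most abundant antisense TE, from 3.58 ± 0.20 to 68.3 ± 15 RPM. Springer and copia, whose small RNAs were mostly sense in Piwi-IP, rose less: springer from 5866 ± 192 to 9267 ± 73 RPM (0.66) and copia from 1651 ± 64 to 2273 ± 201 (0.46). The largest falls were those of invader2, from 84.4 ± 0.87 to 22.5 ± 4.85 RPM (−1.87), and invader3, from 109 ± 2.17 to 42.6 ± 11 (−1.36). They were followed by accord2 (−1.10), Transpac (−0.86) and BS (−0.71), beside 1 copia-type element (−0.78).

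Of 53 TEs tested on the sense strand, 36 passed, 24 higher and 12 lower in CG9754-IP, and rescaled to the same TE total 36 passed, 29 higher and 7 lower. The median log2 change was 0.15, and 0.49 after rescaling. It was 0.03 without CG9754-IP replicate 1 (24 higher, 19 lower) and 0.27 without replicate 2 (27 higher, 13 lower). The falls of hopper (−0.61), gypsy12 (−0.56), INE-1 (−0.52) and Circe (−0.35) lost the call when rescaled, and those of INE-1 without Piwi-IP replicate 1 and of Circe without Piwi-IP replicate 2 did so too. Roo sense levels were 344 ± 34 RPM in CG9754-IP and 349 ± 3.85 in Piwi-IP (−0.03, adjusted p = 0.867), and the rescaled change was 0.32 (adjusted p = 0.0132). Gtwin, Idefix and ZAM were below the sense filter. They had 20.6 ± 1.65, 12.8 ± 1.40 and 10.1 ± 0.40 RPM in CG9754-IP against 1.60 ± 0.46, 1.59 ± 0.47 and 1.30 ± 0.14 in Piwi-IP.

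All 7 elements of the gypsy-group list that were tested on the sense strand rose, with a median log2 change of 2.55. The filter takes the mean of all 6 libraries, so some were tested because of their level in CG9754-IP; with no filter, 12 of the 14 elements in the table rose and 0 fell, with a median of 2.10. As filtered, this list passed camera (adjusted p = 0.0115 with the preset correlation; adjusted p = 0.356 with an estimated correlation, and 0.0501 after rescaling by the median ratio). Its share of the sense signal was 46.1% ± 1.03 in Piwi-IP and 56.9% ± 2.06 in CG9754-IP. Most of that share was springer in both precipitates, so it says little about the other elements of the list. The list leaves out TEs with names like those of its members. Among these, accord2 (−1.10) and gypsy12 (−0.56) fell, while gypsy3 (0.70), gypsy4 (2.91), gypsy6 (1.12) and HMS-Beagle2 (2.42) rose. Of the 7 other gypsy-superfamily elements 6 rose, mdg1 and blood among them, with a median of 1.45 (camera adjusted p = 0.111). Of 9 LINE elements 3 rose and 2 fell, or 5 and 1 after rescaling. Their median of 0.15 was like that over all tested TEs (0.15), while camera, which compares a list with the other TEs, gave the direction as lower. As deposited, the DNA transposon list had 1 rise and 1 fall among 5, the BEL/Pao list 0 rises and 1 fall (diver, −0.68) among 5, and the germline-dominant list 3 rises and 3 falls among 8. After rescaling, the rises were 2, 2 and 4 and the falls 0, 1 and 3. With no filter, camera also called the other gypsy-superfamily list as higher and the DNA transposon list as lower (adjusted p = 0.0331 for both). Adjusted over the list alone, the counts as deposited were the same except for 1 fall among the LINE elements. The copia list had 2 and the telomeric list 0 members above the filter, too few for the test.

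**Figure D2:**
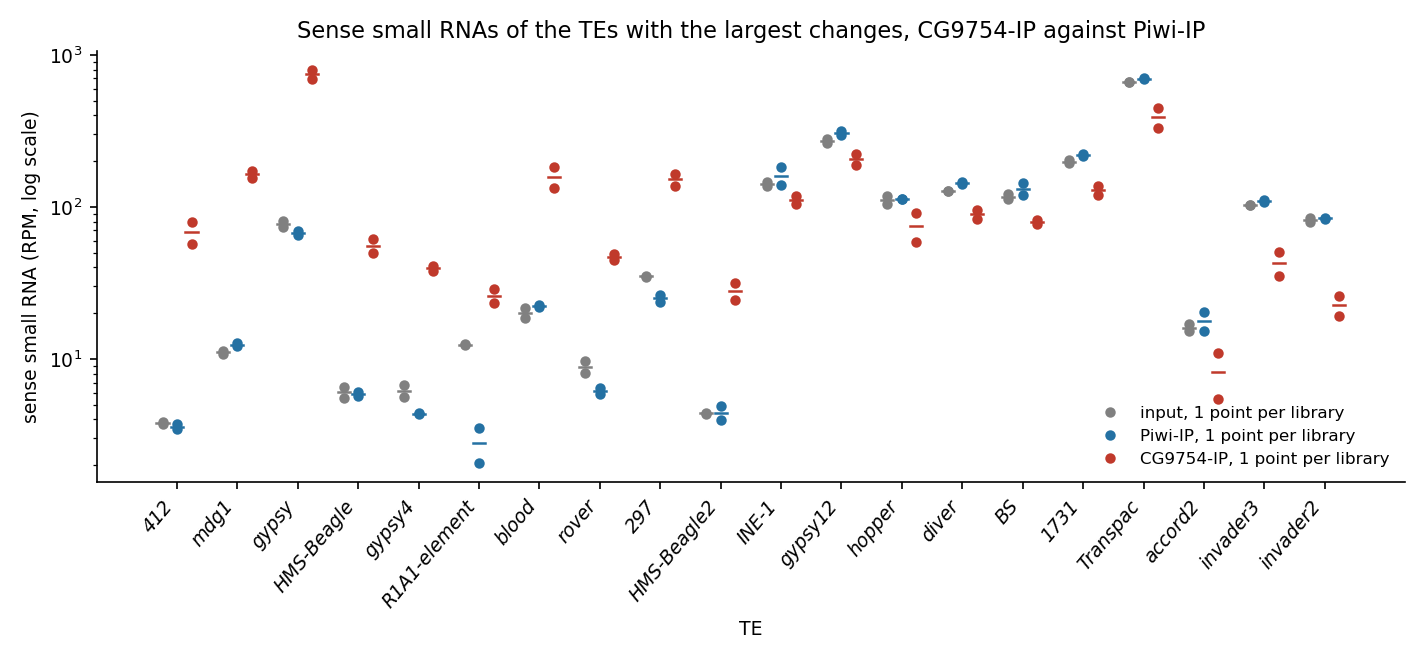
Sense small RNA level (y axis, RPM, log scale) of the 10 TEs with the largest rises and the 10 with the largest falls in CG9754-IP against Piwi-IP, with 1 point per library and a bar at the mean of each group of 2. For mdg1, input and Piwi-IP lie at 11.1 and 12.4 RPM and CG9754-IP at 165 RPM. By contrast, invader2 lies at 82.0 and 84.4 RPM in input and Piwi-IP and at 22.5 RPM in CG9754-IP.

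The balance between the strands of each TE depends little on how a library was scaled, except where 1 strand is near the pseudocount of 1 RPM. This ratio was tested only after the values on both strands had been seen. The log2 ratio of sense to antisense for mdg1 was −10.64 ± 0.0042 in Piwi-IP and −6.33 ± 0.059 in CG9754-IP, a difference of 4.31. It also rose for rover (3.80), gypsy4 (3.40), Idefix (3.32), gypsy (3.29) and gtwin (3.26), all TEs whose small RNAs were nearly all antisense. It fell for TEs with mostly sense small RNAs, among them copia (−1.94), DNAREP1 (−1.65), springer (−1.36) and Transpac (−1.23), and for invader2 (−2.03). By limma 70 of 89 TEs passed against Piwi-IP, 52 higher and 18 lower, and 64 passed against input, 48 higher and 16 lower, or 42 without input replicate 2. With the libraries rescaled to the same TE total the counts were 65 (49 higher, 16 lower) and 60 (44 higher, 16 lower). Between Piwi-IP and input 0 TEs passed by limma, with 12 at an unadjusted p under 0.05, and 2 passed without CG9754-IP replicate 1 or replicate 2.

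Across TEs, mean log2 antisense levels in CG9754-IP and Piwi-IP correlated with Pearson r = 0.982 and Spearman rho = 0.977 over 75 TEs, beside r = 0.999 for Piwi-IP and input and r = 0.993 for the CG9754-IP replicates. Sense levels correlated less, with r = 0.790 and rho = 0.760 over 53 TEs, beside r = 0.989 for Piwi-IP and input and r = 0.986 for the CG9754-IP replicates. TEs are not independent replicates, so these correlations carry no p-value.

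The third comparison sets CG9754-IP against input. On the antisense strand copia (log2 change 2.29), springer (1.99), DNAREP1 (1.65) and G2 (0.97) rose, and mdg3 (−1.37), Dm88 (−0.94), rover (−0.88), Idefix (−0.77), Quasimodo (−0.69), Juan (−0.68) and mdg1 (−0.61) fell. The most abundant TE fell to 25330 ± 2592 RPM (−0.44, adjusted p = 0.00838), a call lost without either input library or Piwi-IP replicate 1. The number-named element fixed in advance also fell (−0.35, adjusted p = 0.0235), a call lost when rescaled to the same TE total or without any 1 of the 4 input and Piwi-IP libraries. FB4, singled out here after its values were seen since it was low in Piwi-IP, did not pass as deposited (0.34, adjusted p = 0.0557) and passed when rescaled (0.52, adjusted p = 0.0129). Gypsy rose from 13062 ± 99 to 17159 ± 2640 RPM (0.39, adjusted p = 0.0337), a call that was lost without any 1 of the 4 input and Piwi-IP libraries or when rescaled by the median ratio. In total 34 of 75 TEs passed limma, 9 higher and 25 lower, with a median of −0.16. After rescaling 34 passed, 19 higher and 15 lower, with a median of 0.01, and by the median ratio 35 passed, 10 higher and 25 lower, with a median of −0.10. The count was 15 without input replicate 1 (6 higher, 9 lower), 14 without input replicate 2 (4 higher, 10 lower), 22 without Piwi-IP replicate 1 (7 higher, 15 lower) and 61 without CG9754-IP replicate 1 (18 higher, 43 lower), and the median lay between −0.28 and −0.10 with each library left out. Roo again changed sign with 1 library, from 0.14 to −0.36 without CG9754-IP replicate 1. A fit of only the 2 groups with rescaling called 21 TEs here and 20 in CG9754-IP against Piwi-IP.

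Against input, 8 of 14 gypsy-group elements fell and 2 rose (springer and gypsy), 5 of 8 other gypsy-superfamily elements fell, and 7 of 16 LINE elements fell and 2 rose; adjusted over the list alone, the falls were 9, 6 and 7, the germline-dominant list had 3 falls and the DNA transposon list 0 rises. After rescaling, 7 gypsy-group elements fell and 3 rose, 4 other gypsy-superfamily elements fell, and 3 LINE elements fell and 5 rose. The telomeric list had 0 calls (median −0.16, and 0.03 after rescaling). The copia list had 2 rises and 1 fall among 3, the BEL/Pao list 1 rise, the DNA transposon list 1 rise (0.32, adjusted p = 0.0425, lost without any 1 of the 4 input and Piwi-IP libraries), and the germline-dominant list 3 rises and 2 falls among 11. Camera called 0 lists (1 at an unadjusted p under 0.05, the other gypsy-superfamily list, adjusted p = 0.208). On the sense strand 34 of 53 TEs passed, 24 higher and 10 lower, and after rescaling 28 higher and 8 lower. With the filter 10 times stricter 10 were higher and 6 lower of 19 tested. As filtered and deposited, mdg1 (3.78), gypsy (3.25) and HMS-Beagle (3.01) were among the largest rises and invader2 (−1.83) and invader3 (−1.28) fell most. R1A1-element rose less than against Piwi-IP (1.00 and 2.85), and FB4, at 1.01 against Piwi-IP, did not pass against input (0.10, adjusted p = 0.617). All 7 tested elements of the gypsy-group list rose, or 13 of 14 with no filter, with a median of 2.08 as filtered. The camera adjusted p was 0.0115, or 0.356 with an estimated correlation and 0.0501 after rescaling by the median ratio. Among TEs with like names outside that list, accord2 (−0.97) and gypsy12 (−0.40) fell. There gypsy3 (0.95), gypsy4 (2.50), gypsy6 (1.08) and HMS-Beagle2 (2.42) rose.

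The knockdown libraries show how the small RNA output of the main somatic piRNA clusters changed when pathway and heterochromatin proteins were depleted. Each condition has 1 library, so there is no replicate error and no test, and the 95% intervals cover counting error only. The values are piRNA counts scaled by the authors to a reference set that the table does not name. They cover 40 windows of 1 kb per cluster on the plus strand of chromosome X (build dm3). In GFP-KD the signal was 66042 in the last flamenco window and 102 in the last 20A window, so the flamenco windows end inside its signal. Sums and ratios given for flamenco are those of these 40 windows, which need not cover the whole cluster. Reads implied over both clusters numbered 3902747 in GFP-KD, 490519 in Armi-KD, 376180 in Piwi-KD, 3305487 in SetDB1-KD and 3387147 in HP1-KD. The mRNA levels of the targeted genes were not analysed here.

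Flamenco (X, 21500001 to 21540000), the main source of antisense piRNAs against gypsy-type elements in follicle cells, had a signal in Armi-KD of 0.0666 times that of GFP-KD (95% interval 0.0663 to 0.0668), which is 15.02-fold lower. Armi is an RNA helicase of piRNA biogenesis. In Piwi-KD the ratio was 0.0662 (0.0659 to 0.0665), or 15.1-fold lower. The sum of cluster 20A (X, 21390001 to 21430000) was 0.125 times that of GFP-KD in Armi-KD (0.124 to 0.125) and 0.112 times in Piwi-KD (0.111 to 0.113). The clusters differed little in their median window ratio, at 0.0651 for flamenco and 0.0661 for 20A in Armi-KD and 0.0621 and 0.0636 in Piwi-KD. The higher sums of 20A went with 7 of its windows, set apart after their values were seen, which held 48.7% of its signal in Armi-KD and 44.4% in Piwi-KD, against 14.1% in GFP-KD; the other 29 windows with enough reads had a median ratio of 0.0528 and 0.0521. In SetDB1-KD, which targets a histone methyltransferase, the ratio was 0.858 (0.857 to 0.860) for flamenco and 0.903 (0.900 to 0.906) for 20A. In HP1-KD, which targets the protein that binds methylated histone tails, it was 1.172 for flamenco (1.171 to 1.174) and 0.889 for 20A (0.886 to 0.892).

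By windows, 71 of the 72 with enough reads were at least 2-fold lower in Armi-KD and 70 of 72 in Piwi-KD, with 0 higher in either. The lowest ratios in Armi-KD were 0.0184 at 20A 21428001 (3 against 103 reads, 95% interval 0.00373 to 0.0552), 0.0371 at flamenco 21520001 and 0.0384 at 20A 21422001. Those in Piwi-KD were 0.0304 at 20A 21391001 (4 against 104 reads, 0.00814 to 0.0803), 0.0430 at 20A 21422001 and 0.0444 at 20A 21407001. SetDB1-KD had 0 windows past the 2-fold limit downwards and 1 of 73 upwards, at flamenco 21502001, where 164 against 52 reads gave a ratio of 3.23 (2.35 to 4.51). HP1-KD had 0 of 72 past the limit in either direction.

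These ratios rest on the authors' scaling. Rescaling both clusters of each library to the same total, which removes any change common to them, put flamenco at 0.840 in Armi-KD and 0.868 in Piwi-KD and 20A at 1.57 and 1.47, and left 4 and 1 windows at least 2-fold lower, with 12 higher in each. Each rescaling multiplies both clusters of a library alike, so it cannot change their order, and the size of a loss that both shared cannot be read from the table without the authors' reference set.

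**Figure D3:**
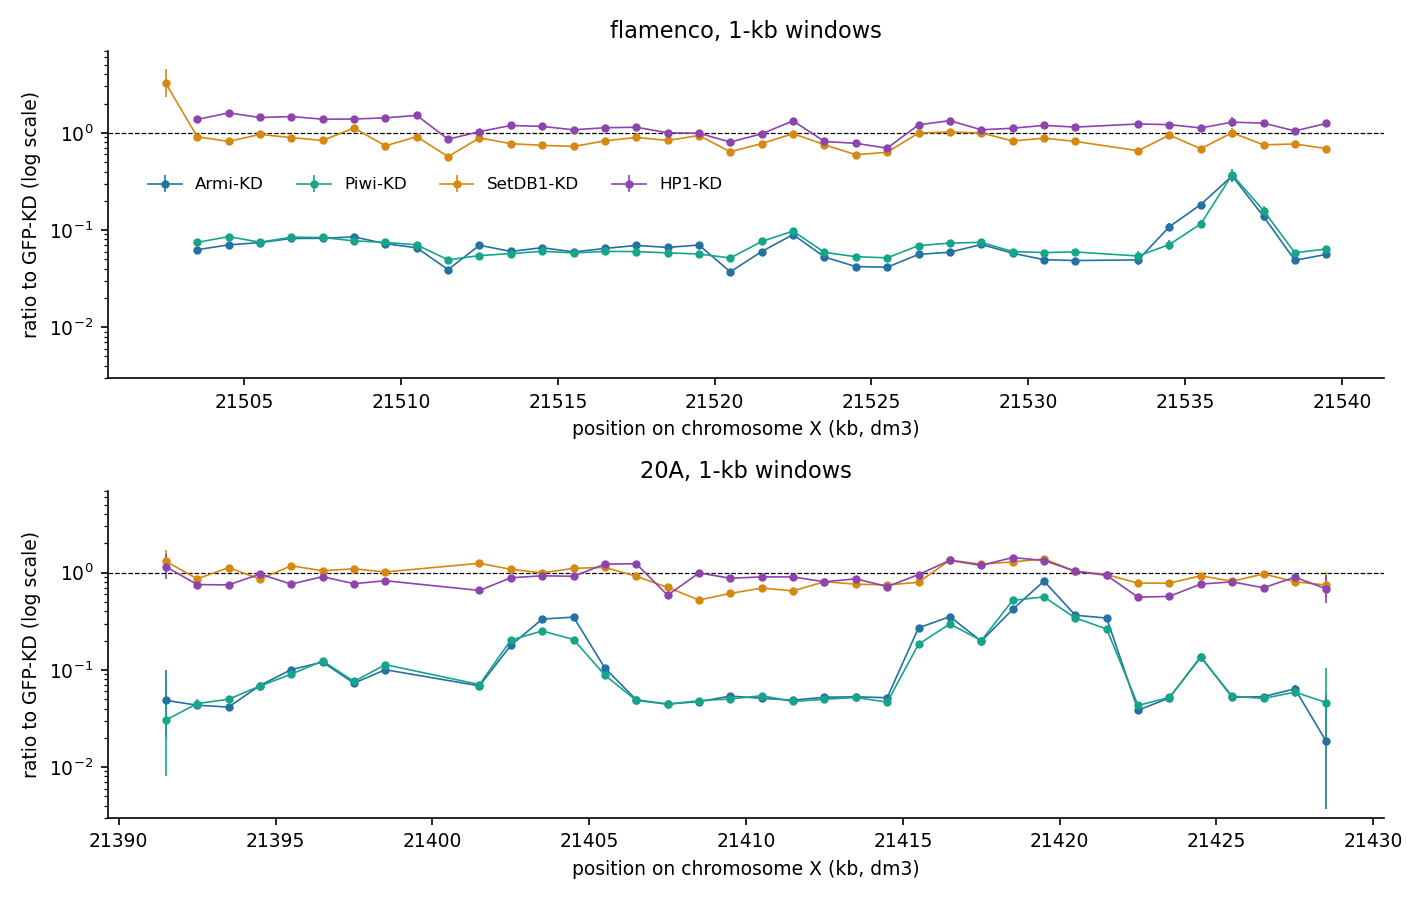
Ratio of small RNA signal to GFP-KD (y axis, log scale) in 1-kb windows of flamenco (top) and 20A (bottom) against position on chromosome X (x axis, kb, dm3), with 1 library per knockdown and bars for the 95% counting interval. On the authors' scaling, Armi-KD and Piwi-KD lie near 0.06 over most windows, with windows of 20A that reach 0.822 and 0.564, while SetDB1-KD and HP1-KD lie near 1.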

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

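The results for the sense strand, the strand ratio, the single clusters and the windows, the rescaled fit of only the 2 groups compared, the rescaling by the median ratio over TEs, and the lists with no filter, were added after the data were seen. Of 2350 values of named TEs and lists under the alternatives, 2080 kept their direction and their side of the threshold, whatever their change in size. With the direction kept, 114 lost and 63 gained a call. The direction changed in 84 with no call in either setting, and in 9 with a call, which are given as reversed. Of 280 counts, ratios and correlations, 192 stayed within their limits. Where no cause is named, the cause was not tested.

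The count of antisense TEs in Piwi-IP against input (1) depended most on the estimate of the spread: it was 46 in a fit of only these 2 groups, 9 in that fit with rescaled libraries, 3 with no filter, 0 with the filter 10 times stricter (fewer TEs tested), 2 on sense reads and 2 on the sum of both strands, and 0 to 47 with each library left out. The fit of only the 2 groups called 24 TEs in CG9754-IP against input and 40 in CG9754-IP against Piwi-IP, and 21 and 20 when rescaled. The main fit called 34 and 47. With each library left out these counts were 14 to 61 and 33 to 66. On the sense strand the stricter filter gave 0 TEs in Piwi-IP against input and 16 in both CG9754-IP contrasts, with fewer TEs tested, and the ranges with each library left out were 2 to 5, 30 to 38 and 32 to 43. In the strand ratio of Piwi-IP against input, the fit of only the 2 groups called 2 TEs and a pseudocount of 10 called 1; with each library left out the counts of the 3 contrasts were 0 to 2, 42 to 69 and 53 to 74. A group left with 1 library was assumed to vary like the others.

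Lists past the camera threshold in Piwi-IP against input numbered 0 with an estimated correlation, 0 with no filter and 1 to 2 with each library left out, and on the sense strand 0 in both CG9754-IP contrasts with an estimated correlation or after rescaling by the median ratio, and 3 in both with no filter. Values that reversed were those of gtwin antisense against Piwi-IP (0.15 rescaled to the same total, 0.0231 by the median ratio), roo sense against Piwi-IP (0.32 and 0.1934), roo antisense with each library left out (lowest −0.40 and highest 0.60 against Piwi-IP, −0.36 and 0.64 against input) and the median of the DNA transposon list in Piwi-IP against input (−0.11 with either) and of its sense values in CG9754-IP against input (−0.1558 with no filter). Pearson r of CG9754-IP and Piwi-IP was 0.990 with no filter, 0.977 without the 5 most abundant TEs and 0.978 to 0.983 with each replicate by itself on the antisense strand, and 0.923, 0.648 and 0.770 to 0.804 on the sense strand.

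A replicate block, which assumes that libraries with the same number form a pairing, gave 1 TE in the strand ratio of Piwi-IP against input and 2 lists (DNA transposons and copia) in that contrast. The labels do not say that the numbers pair the libraries. The deviations of replicates from their group means correlated with r of 0.034 (input and Piwi-IP), 0.034 (input and CG9754-IP) and 0.086 (Piwi-IP and CG9754-IP) on the antisense strand, and 0.260, 0.102 and −0.131 on the sense strand, so the strands differ and the numbers were not taken as a pairing.

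For the clusters, rescaling to the same total sets the sum of both to 1 in all 4 knockdowns by construction, and gave 0.8399, 0.8683, 0.9887 and 1.056 for flamenco and 1.571, 1.47, 1.04 and 0.8008 for 20A in Armi-KD, Piwi-KD, SetDB1-KD and HP1-KD in that order. Rescaling by the median window ratio gave 1.218, 1.229, 1.003 and 1.094 for the sum, 1.023, 1.067, 0.9916 and 1.155 for flamenco and 1.914, 1.806, 1.043 and 0.8763 for 20A. Without flamenco the sum was 0.1246, 0.1121, 0.9031 and 0.8892. With the first and the second rescaling, Armi-KD had 4 and 1 windows lower and 12 and 14 higher, and Piwi-KD 1 and 1 lower and 12 and 13 higher. At a 1.5-fold limit SetDB1-KD had 8 windows lower and HP1-KD 4 lower and 2 higher. With a minimum of 10 reads SetDB1-KD and HP1-KD had 2 windows higher each, and with a minimum of 1000 SetDB1-KD had 0, so its 1 higher window rests on low counts. The planned edgeR and DESeq2 tests and TMM factors were not run, so how the calls depend on a count model was not tested. Depth limits the windows with few reads, and the single library per knockdown limits every cluster result.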

Other observations

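All tests in this part were chosen after the results were seen. In HP1-KD the 8 flamenco windows from 21503001 to 21511000 had a median ratio to GFP-KD of 1.43 (1.38 to 1.60), against 1.13 (0.696 to 1.34) in the other 28 windows past the minimum. In Armi-KD and Piwi-KD, 7 windows of 20A kept more than 3 times the median ratio of the cluster in both libraries: those that start at 21403001, 21404001, 21416001 and the 4 from 21418001 to 21422000. Their median ratio was 0.353 in Armi-KD and 0.297 in Piwi-KD, against 0.0528 and 0.0521 in the other 29 windows. These others include neighbours that missed the limit in only 1 of the knockdowns. In Armi-KD and Piwi-KD their ratios were 0.179 and 0.202 at 21402001, 0.271 and 0.184 at 21415001, and 0.198 and 0.200 at 21417001. The limit therefore cuts into longer stretches of kept signal. In flamenco the highest ratios were 0.361 and 0.371, both at 21536001. The 7 windows of 20A held 14.1% of the 20A signal in GFP-KD, 48.7% in Armi-KD and 44.4% in Piwi-KD, and under 18% in SetDB1-KD and HP1-KD.

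Technical explanations for the changed strand balance in CG9754-IP were weighed first. Carry-over of input-like RNA would keep the ratio of sense to antisense between those of input and Piwi-IP. Of all 89 TEs tested, past the threshold or not, 72 went against that. In these, both CG9754-IP libraries lay on 1 side of the range of the 4 input and Piwi-IP libraries. Chance gives 13.3% for 1 TE by itself, but all TEs share the same libraries. A shift common to a library would move many together, so the 72 are not independent cases. Reads given to the wrong strand at a fixed rate would add a like share of the stronger strand to the weaker one, but that share spanned 465-fold, from 0.0401% to 18.7%, over the 27 of the 70 TEs past the threshold with at least 1000 RPM on their stronger strand in CG9754-IP, and lay between −0.275% and 18.7% over all 30 tested TEs of that level. Sense fragments of TE transcripts alone would not lower the ratio, which fell for 18 of the 70 TEs. A hypothesis that stays open is that the CG9754 precipitate may hold small RNAs of both strands in addition to those bound by Piwi. Of the 70 TEs, 65 moved towards a ratio of 1, and 62 ended closer to it. The 65 were 49 of 51 with more antisense and 16 of 19 with more sense small RNA in Piwi-IP. This restates the pattern that prompted the hypothesis, over TEs called for that change, so it is no test of it. Read lengths and a mock precipitate, which would show what these RNAs are, were not among the values used here.

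For the 20A windows that kept signal, counting noise is argued against by windows chosen in 1 knockdown and measured in the other: the lowest 95% bound there was 2.62 times the median window ratio, over 8 windows chosen in Armi-KD and 9 chosen in Piwi-KD. Both ratios share the GFP-KD library, in which these windows had at least 8452 reads (exact Poisson 95% interval 8273 to 8634), too many for counting error in it to raise a ratio by that much; how GFP-KD would vary between libraries is not known. An even background would add alike to the 25 other windows with as much signal in GFP-KD. The signal above the median ratio in the 7 windows was at least 2.42 times the lowest signal left in those. The 7 windows were chosen for a high ratio in these same libraries, which largely fixes this outcome. It is therefore no separate evidence against an even background, and no conclusion is drawn from it. Small RNAs that do not depend on Armi and Piwi, or reads shared with other loci, cannot be told apart from these tables: the 48.7% of the 20A signal of Armi-KD that lies in these windows would follow from either, since the table gives neither read lengths nor unique mapping. No biological explanation was tested, and each knockdown has 1 library.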
